A study of Mus musculus with 12 samples.

How the data were processed

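Transcript levels were measured on 12 one-colour arrays of the Affymetrix mouse type, 1 array per sample, in 4 groups of 3. The groups crossed genotype (wild type, WT, or bERKO, which lacks estrogen receptor beta) with hormone treatment (pregnant mare serum gonadotropin, PMSG, alone, or PMSG followed by human chorionic gonadotropin, hCG). Per the labels, granulosa cells were laser-captured from 3-week-old mice, and their RNA was isolated with a PicoPure kit. Per the labels, 25 ng of total RNA was amplified with the NuGEN Ovation Pico WTA system and biotinylated with the NuGEN Encore module. The labels call the arrays of a group biological replicates; the number of animals behind each array is not given in the sources used here.

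The deposited values were linear intensities, 1 per probe set, and the authors had scaled every array to 1 common level, a 2% trimmed mean of 500.0. The software that made these signals is not given in the sources used here. The table held 45101 probe sets, of which 64 control probe sets were left out. Gene names came from a table pairing probe sets with genes: 34945 probe sets named 1 gene, 932 named several genes and 9160 were not listed, and only the first kind was tested. Of these, 34741 also matched a current gene record, and 0 symbols needed an update.

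Values were analysed as log2(intensity + 16), so a log2 change understates the change of dim genes. The array medians on that scale ran from 6.02 to 7.00, a gap of 0.98. That exceeded the limit of 0.5 fixed in the plan, so the 45037 remaining probe sets were quantile normalized first. Each gene was represented by its one-gene probe set with the highest mean over the 12 arrays, which left 18193 genes, 9010 of them with several probe sets. No filter on dim genes was applied. The number of arrays limits the precision of every value.

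Group means were fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3) over all 12 arrays, with 1 shared estimate of the spread per gene moderated by eBayes. The contrasts were bERKO minus WT after PMSG, bERKO minus WT after hCG, their average, hCG minus PMSG in WT, hCG minus PMSG in bERKO, and the difference between those responses (the interaction). P-values were adjusted by Benjamini-Hochberg within each contrast, tests were two-sided, and an adjusted p under 0.05 counted as passing. The tests, the gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

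Gene groups were 21 fixed lists of 368 genes, 336 of them measured. They covered cumulus expansion genes and EGF-like ligands, ovulatory transcription factors, immediate early genes, ovulatory proteases and inhibitors, preovulatory granulosa differentiation, steroidogenesis, cholesterol synthesis and uptake, proliferation, cAMP signalling components, nuclear steroid receptors and coregulators, Wnt and TGF-beta family signalling, hypoxia and glycolysis, and heat shock and RNA-handling stress. They also covered markers of theca and interstitium, stroma and smooth muscle, endothelium, leukocytes, oocyte, erythrocyte, surface epithelium and luteal cells. Each list was tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Adjustment ran over the 105 tests of 21 lists in 5 contrasts (all but the average). Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Of the 49 list calls, 0 had a mean, a median and a test of different sign; among the 56 tests without a call, 18 did. Of the list calls, 0 held with an estimated correlation.

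Named genes followed a fixed rule. Per contrast, it took the 8 largest rises and the 8 largest falls among genes that passed and whose groups did not overlap, or, where fewer than 5 genes passed, the 5 smallest p-values in each direction. It added the 4 members with the smallest p of each list with a call, and up to 3 passing members of each other list. It also added 8 genes in every contrast; 2 of the 8 genes had no one-gene probe set in the table used and are not analysed here. Predicted and unnamed genes were skipped. Genes outside this rule, among them list members beyond those of the rule in a contrast, were chosen after their values were seen.

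The size of the hCG response was the mean over genes called in the response averaged over both genotypes, each signed by that average response. The genotypes were compared by exact permutation of the genotype labels within each treatment, over 400 arrangements. The 2 responses share no array, and their overlap was set against that of independent lists. Their tests do share the spread of each gene, so genes with a small spread can pass in both. Independent lists can therefore understate the overlap expected by chance. The fit was tested on simulated data with changes put into 200 genes, in 10 draws per comparison. Of 67 genes with a log2 change of 2, it recovered on average 52.4% for the genotypes after PMSG, 52.1% after hCG, 82.2% for their average, 49.0% for hCG in WT, 54.2% for hCG in bERKO and 14.6% for the interaction. Alternatives covered the scaling between arrays, filters on dim genes, the variance model, array weights, the samples in the fit, the replicate number as a block, the threshold, the choice of probe set, the offset and leaving out each array in turn. The values as deposited, and the fit without the 2 arrays that stood apart, were added after seeing the data.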

Results

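Granulosa cells of preovulatory follicles were profiled from WT and bERKO mice. PMSG, which acts like follicle-stimulating hormone, had been given 48 h before collection. The hCG groups also received hCG, which acts like luteinizing hormone, 4 h before collection. Each of the 4 groups held 3 arrays. Median signal per array ran from 49.1 (bERKO PMSG replicate 3) to 112.8 (WT hCG replicate 3). Between 18.7% and 30.0% of the signals of an array lay under 16. Below, a change is a difference of mean log2(intensity + 16), given with its standard error (SE) where one is printed, over 3 arrays per group, and an adjusted p comes from limma or its camera test.

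A pair of arrays stood apart. The Gapdh 3'/5' control ratio, which rises as RNA is degraded or copied incompletely, was 23.74 on bERKO PMSG replicate 3 and 32.16 on WT hCG replicate 1, against 4.72 to 11.19 on the other arrays. The first principal component (36.8% of the variance) separated the hCG arrays from the PMSG arrays, except that WT hCG replicate 1 lay at -24.3, between WT PMSG (-44.4 to -36.1) and the other WT hCG arrays (27.2 and 32.5). On WT hCG replicate 1, some genes of the ovulatory response were far below their level on replicates 2 and 3 of the group. Pgr, the progesterone receptor, measured 5.21 there against 13.10 and 13.38, and Ptgs2, the prostaglandin synthase needed for ovulation, measured 8.18 against 12.23 and 13.62. Others were not, such as Cebpb (12.10 against 11.87 and 11.25) and Nr4a1 (10.09 against 11.51 and 8.87).

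**Figure D1:**
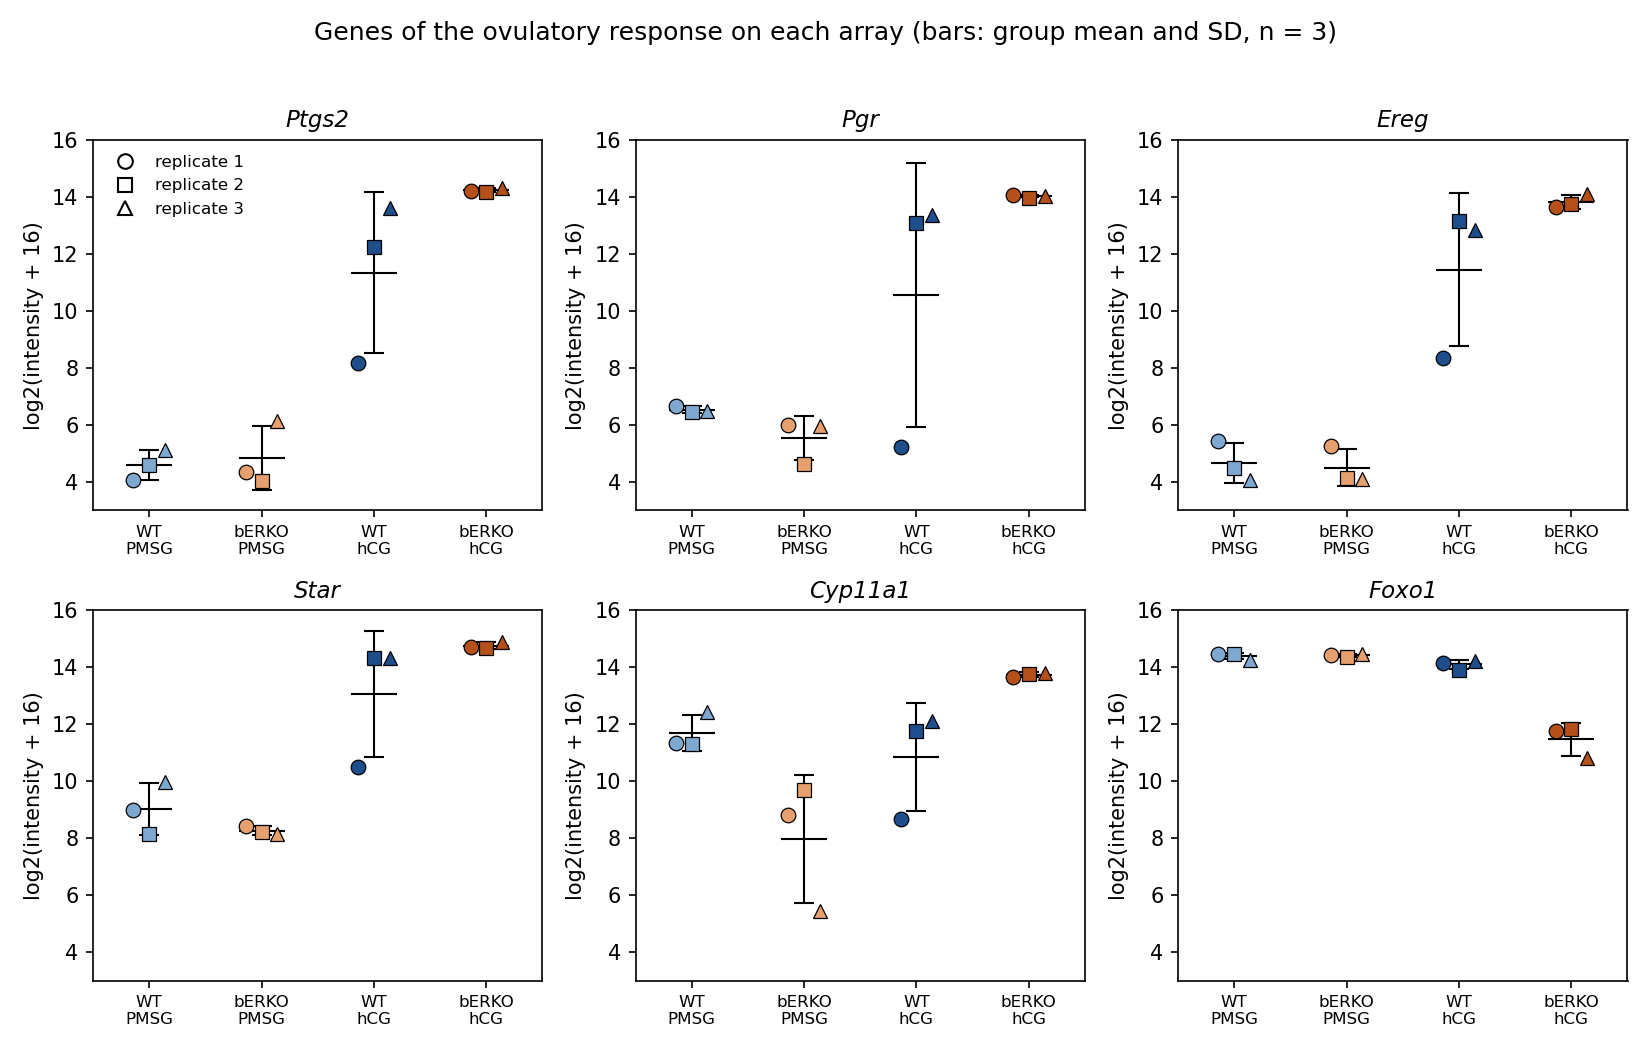
Levels of 6 genes on each array as log2(intensity + 16) on the vertical axis, by group on the horizontal axis. Symbols mark the replicates and bars show the group mean and SD of 3 arrays. Pgr stood at 5.21 on WT hCG replicate 1 and at 13.10 and 13.38 on the other WT hCG arrays, while the 3 bERKO hCG arrays had a mean of 14.03 (SD 0.05).

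The first comparison addressed how bERKO granulosa cells differed from WT before the ovulatory signal. Esr2, the gene of the missing receptor, had a mean of 9.56 ± 0.69 (SD, n = 3) in WT and 8.32 ± 0.28 (SD, n = 3) in bERKO after PMSG, a change of -1.24 (SE 0.37) that did not pass in limma (adjusted p = 0.307). After hCG its change was -0.66, again not passing in limma (adjusted p = 0.397), and -0.40 without WT hCG replicate 2. Esr2 had 1 probe set, and where it lies relative to the disrupted part of the gene is not given in the sources used here, so this checks the labels only in part. Cadm3, a cell adhesion molecule, was lower in bERKO by -4.28 (SE 0.47), and Igk, the immunoglobulin kappa light chain, by -4.38 (SE 0.49), each at an adjusted p of 0.0123. On the bERKO PMSG arrays Cadm3 (4.05, 4.15 and 4.05) and Igk (5.07, 4.17 and 4.17) lay at or near the floor of 4 set by the offset. The size of these changes depends on the offset, and with log2(value + 1) both calls were lost. The 4 probe sets of Igk disagreed, with changes from -4.38 to 0.40. Esr1, estrogen receptor alpha, had a change of 1.31 (SE 0.32) that did not pass (adjusted p = 0.257).

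Genes near the threshold after PMSG did not pass. Among those with higher means in bERKO were Pxdc1 (3.41), the pluripotency factor Pou5f1 (3.13, adjusted p = 0.0786), Ak7 (2.87), Hecw2 (2.24) and the anion exchanger Slc26a3 (1.81). Pou5f1 was highest within WT PMSG on replicate 3, as were the oocyte markers described below, though not within bERKO PMSG. Whether it came from captured oocyte RNA was not tested. Among those with lower means were the inhibitor of DNA binding Id3 (-2.05), the aryl hydrocarbon receptor Ahr (-1.87) and the ephrin receptor Epha5 (-3.78, adjusted p = 0.0614). Fshr, the FSH receptor, had a change of -0.74, and Ptgs2, Pgr and the androgen-synthesis enzyme Cyp17a1 had changes of 0.25, -1.0 and 0.36, none passing. The sign of the Ptgs2 value turned without WT PMSG replicate 1 (-0.03) or bERKO PMSG replicate 3 (-0.41), and that of Cyp17a1 without WT PMSG replicate 2 (-0.03). With 1 array left out, Fshr ran from -1.16 to -0.13, Ptgs2 from -0.41 to 0.65, Cyp17a1 from -0.03 to 0.82, and Pgr was at -0.55 without bERKO PMSG replicate 2.

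Steroidogenic genes as a group were lower in bERKO after PMSG. The 13 measured genes had a mean change of -0.67 (camera adjusted p = 0.00173; adjusted p = 0.128 with an estimated correlation). 0 passed over all genes and 3 were lower adjusted over the list alone: Cyp11a1, which cleaves cholesterol to pregnenolone, with a change of -3.71 (SE 1.04), the progesterone-degrading enzyme Akr1c18 with -1.55 and Hsd11b2 with -1.19. Akr1c14, at -0.47, did not pass. Cyp11a1 measured 8.82, 9.68 and 5.44 on the bERKO PMSG arrays, and its change was -2.44 without replicate 3, the array with a Gapdh 3'/5' ratio of 23.74. Akr1c14 changed sign, to 0.09, with each array centred on its median. Luteal markers were lower as a group, by a mean of -1.35 over 8 genes (camera adjusted p = 0.00214; adjusted p = 0.199 with an estimated correlation), 3 of them lower adjusted over the list alone. The 3 were Sfrp4, a secreted Wnt antagonist (-5.30, SE 1.23), the prostaglandin F receptor Ptgfr (-2.52) and Akr1c18. Timp3 did not pass (-0.95, and -0.38 without bERKO PMSG replicate 3).

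Preovulatory granulosa differentiation genes were lower as a group by a mean of -0.36 over 22 genes (camera adjusted p = 0.00748; adjusted p = 0.348 with an estimated correlation), with 0 members passing adjusted over the list alone. Their members with the smallest p were Grem1, a BMP antagonist (-2.18), Npr2, the receptor for C-type natriuretic peptide (-1.22), follistatin (Fst, -0.81) and Pappa (-1.87). Without bERKO PMSG replicate 3 the mean of the list was -0.19, Grem1 -1.25 and Pappa -1.24. Wnt and TGF-beta family genes had a mean of -0.33 over 25 genes (camera adjusted p = 0.033; adjusted p = 0.128 with an estimated correlation), with 1 higher and 2 lower adjusted over the list alone. The 3 were Gdf9 (2.28), an oocyte growth factor, Id3 and Sfrp4. Lef1 did not pass (1.37, and 0.89 without WT PMSG replicate 2). Hypoxia and glycolysis genes had a mean of -0.25 over 21 genes (camera adjusted p = 0.00748; adjusted p = 0.395 with an estimated correlation), with 1 higher adjusted over the list alone, Adm (2.40). Pfkfb3 (-1.55), Ndrg1 (-0.96) and the lactate dehydrogenase Ldha (-0.60) did not pass. Without bERKO PMSG replicate 3 the mean was -0.09 and Ldha -0.38.

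Oocyte markers were higher in bERKO after PMSG. The 13 measured genes had a mean change of 2.46 (camera adjusted p = 7.87e-12; adjusted p = 0.128 with an estimated correlation), and 12 of them were higher adjusted over the list alone while 0 passed over all genes. Members were Zp3, a zona pellucida protein (3.60), Oosp1 (2.94, and 1.94 without WT PMSG replicate 1), Nlrp5 (2.78) and Gdf9 (2.28). Their mean level was 9.02, 8.90 and 10.33 on the bERKO PMSG arrays and 5.93, 6.42 and 8.51 on the WT PMSG arrays. The highest, bERKO PMSG replicate 3, was the array with a Gapdh 3'/5' ratio of 23.74.

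After PMSG, limma called 0 genes higher and 2 lower in bERKO of 18193, with 1733 at an unadjusted p under 0.05. 14.7% of all genes had groups that did not overlap, where chance gives 10%. The count was 0 without bERKO PMSG replicate 3, 1 without WT PMSG replicate 1 or 2, 12 without bERKO PMSG replicate 2, 26 without WT PMSG replicate 3, and 8 and 14 without WT hCG replicate 1 or 3, which enter through the shared spread. The list call was lost for preovulatory differentiation without WT PMSG replicate 1 (adjusted p = 0.0649) or bERKO PMSG replicate 3 (0.0808). It was lost for hypoxia and glycolysis without the same arrays (0.0614 and 0.222), and for Wnt and TGF-beta genes without WT PMSG replicate 2 or 3 (0.0545 and 0.176) or bERKO PMSG replicate 2 (0.14).

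The second comparison addressed how the genotypes differed 4 h after hCG. Genes of the preovulatory state were lower in bERKO: Foxo1, a transcription factor lost as granulosa cells differentiate, by -2.64 (SE 0.29, adjusted p = 0.00222), the inhibin subunit Inhbb by -2.74 (SE 0.28, adjusted p = 0.0015), Gata4 by -2.58 (SE 0.35, adjusted p = 0.00642) and Fshr by -2.62 (SE 0.50, adjusted p = 0.0207). Foxo1 measured 14.10 ± 0.17 (SD, n = 3) in WT and 11.46 ± 0.58 (SD, n = 3) in bERKO after hCG. The preovulatory list had a mean change of -0.75 over 22 genes, with 0 higher and 6 lower over all genes and 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.000217; adjusted p = 0.19 with an estimated correlation).

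Lists of the ovulatory response were higher in bERKO after hCG, by less without WT hCG replicate 1, the WT array that stood apart. Of 17 cumulus expansion genes and EGF-like ligands, 2 were higher over all genes and 7 adjusted over the list alone (mean 1.56, camera adjusted p = 4.28e-05; adjusted p = 0.166 with an estimated correlation). Hapln1, a matrix link protein, was higher by 2.06 (SE 0.44, adjusted p = 0.0336) and Il6 by 1.38 (SE 0.30, adjusted p = 0.0361), while Has2, the hyaluronan synthase of cumulus expansion (2.65), and its receptor Cd44 (1.85) did not pass. On the WT hCG arrays Hapln1 (4.36, 4.38 and 4.68) and Il6 (4.04, 4.86 and 4.26) lay near the floor of 4 set by the offset. Hapln1 measured 6.53, 5.26 and 6.52 in bERKO after PMSG. Its 4 probe sets had changes from 0.02 to 2.06 between the genotypes after hCG. Of 20 ovulatory transcription factors, 2 were higher over all genes and 5 adjusted over the list alone (mean 0.90, camera adjusted p = 0.00173; adjusted p = 0.128 with an estimated correlation), namely Bcl6 (1.79, SE 0.34) and Fosl1 (2.69, SE 0.55) over all genes. Of 19 immediate early genes, 1 was higher over all genes, Fosb (2.17, SE 0.50), and 8 adjusted over the list alone (mean 1.18, camera adjusted p = 1.28e-05; adjusted p = 0.229 with an estimated correlation). Of 16 ovulatory proteases and inhibitors, 1 was higher over all genes, the matrix protease Adamts4 (3.10, SE 0.74), and 7 adjusted over the list alone (mean 1.05, camera adjusted p = 0.000191; adjusted p = 0.128 with an estimated correlation). Other members did not pass over all genes: Crem 2.30, Pparg 1.94, Zfp36 1.97, Egr2 2.85, Nr4a3 1.71, Timp1 2.91, Plaur 1.5 and Plau 1.18. Ptgs2 (2.89, adjusted p = 0.175), Pgr (3.46, adjusted p = 0.294) and Cyp17a1 (-0.38) did not pass either. Without WT hCG replicate 1 the list means were 0.84 (cumulus genes, which averaged 6.79 on that array and 8.74 and 9.13 on the other WT hCG arrays), 0.56 (transcription factors) and 0.78 (immediate early genes), with the calls kept. Single genes were then at 0.79 (Pgr), 1.31 (Ptgs2), 1.75 (Has2), 1.19 (Crem), 1.15 (Pparg), 1.29 (Zfp36), 1.81 (Egr2), 1.07 (Nr4a3) and 1.84 (Timp1). Cyp17a1 ran from -0.60 to -0.03 with 1 array left out.

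Sterol genes were higher in bERKO after hCG. Of 16 genes of cholesterol synthesis and uptake, 7 were higher over all genes and 12 adjusted over the list alone, with 0 lower (mean 1.30, camera adjusted p = 1.79e-09; adjusted p = 0.128 with an estimated correlation). Examples were Fdps (2.43, SE 0.46), Idi1 (1.86, SE 0.34), Insig1 (1.84, SE 0.29), which holds back sterol synthesis when cholesterol is plentiful, and the cholesterol carrier Stard4 (1.58, SE 0.28). The 2 probe sets of Fdps ran from 0.13 to 2.43. Steroidogenesis had no list call (mean 0.88, camera adjusted p = 0.064; mean 0.55 without WT hCG replicate 1), but Hsd17b7 (3.38, SE 0.42) and the lipoprotein receptor Scarb1 (1.20, SE 0.25) were higher and Akr1c14 (-1.60, SE 0.22) was lower. Luteal markers were higher as a group: 1 of 8 over all genes and 4 adjusted over the list alone (mean 1.75, camera adjusted p = 8.28e-05; adjusted p = 0.128 with an estimated correlation), with Ptgfr at 4.54 (SE 0.79, adjusted p = 0.0147). Sfrp4 (3.76, and 1.90 without WT hCG replicate 1), Akr1c18 (1.62) and the cell cycle inhibitor Cdkn1a (0.93) did not pass.

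The largest rise over WT after hCG was that of Mpzl2, an adhesion protein, at 7.04 (SE 0.52, adjusted p = 0.000334). On the WT hCG arrays it measured 4.06, 4.04 and 4.03, at the floor of 4 set by the offset, so the size of this rise depends on the offset. Others were the drug efflux pump Abcb1b (5.65, SE 1.17), Cemip, which takes part in hyaluronan breakdown (4.98, SE 1.03), the lipase Lipg (4.79, SE 0.90), Bhmt (4.78, SE 0.86), Adcyap1, which encodes the peptide PACAP (4.58, SE 1.08), and Lrrn3 (4.40, SE 0.69). On replicate 3, Abcb1b, Cemip, Lipg and Bhmt were highest within WT PMSG and lowest within bERKO hCG, unlike Mpzl2, Adcyap1 and Lrrn3. The mean of the stromal markers had that array pattern too (5.64, 5.99 and 7.74 in WT PMSG, 8.19, 8.06 and 7.20 in bERKO hCG). Among other genes named here, Ptgfr, Sfrp4, Hsd17b7, Idi1 and Pde3b had the same order of arrays. Whether the signal of any of these genes came from other captured cells was not tested. The largest falls were those of Limch1 (-3.88, SE 0.63), Tdrd5 (-3.86, SE 0.49), Itih5 (-3.76, SE 0.76), Rassf2 (-3.50, SE 0.55), the tight junction protein Cldn11 (-3.43, SE 0.70), Nat8f3 (-3.39, SE 0.32), the corepressor Cbfa2t3 (-3.35, SE 0.33) and Smim10l2a (-3.31, SE 0.60). In lists without a call, the phosphodiesterases Pde4b (2.54, SE 0.38) and Pde3b (2.54, SE 0.52), the prolyl hydroxylase Egln3 (2.32, SE 0.40) and Ndrg1 (1.77, SE 0.40) were higher, and Tgfbr3 (-1.55, SE 0.28), Bmpr1b (-1.40, SE 0.32), Id3 (-1.25, SE 0.28), Aldh1a1 (-1.28, SE 0.28) and the replication factor Mcm6 (-1.20) were lower. Probe sets disagreed in sign for Pde4b (-0.25 to 2.54), Ndrg1 (-0.33 to 1.77) and Mcm6 (-1.47 to 0.30). Those of Limch1 had the same sign but ran from -3.88 to -0.09. Proliferation, cAMP, Wnt and TGF-beta, hypoxia, heat shock, nuclear receptor, theca, oocyte, erythrocyte and surface epithelium lists had no call, with camera adjusted p from 0.0552 (oocyte) to 0.945 (surface epithelium).

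Markers of other cell types were higher on the same bERKO hCG arrays. Of 12 endothelial markers, 4 were higher over all genes and 6 adjusted over the list alone (mean 1.59, camera adjusted p = 5.05e-08; adjusted p = 0.11 with an estimated correlation): Emcn by 2.56 (SE 0.35), VE-cadherin (Cdh5) by 3.04 (SE 0.50), and the VEGF receptors Kdr by 2.57 (SE 0.59) and Flt1 by 1.55 (SE 0.36). Stromal and smooth muscle markers (15 genes, mean 1.27, camera adjusted p = 0.00117; adjusted p = 0.371 with an estimated correlation) and leukocyte markers (16 genes, mean 0.85, camera adjusted p = 0.00217; adjusted p = 0.15 with an estimated correlation) were higher as groups, each with 0 members over all genes and 2 adjusted over the list alone. Their members with the smallest p were Pdgfrb (3.24), Col1a1 (2.99), Lum (2.02) and Col3a1 (3.51), and Cd52 (1.93), Lyz2 (2.29), C1qc (1.53, from 1.01 to 2.31 with 1 array left out) and C1qb (3.01).

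**Figure D2:**
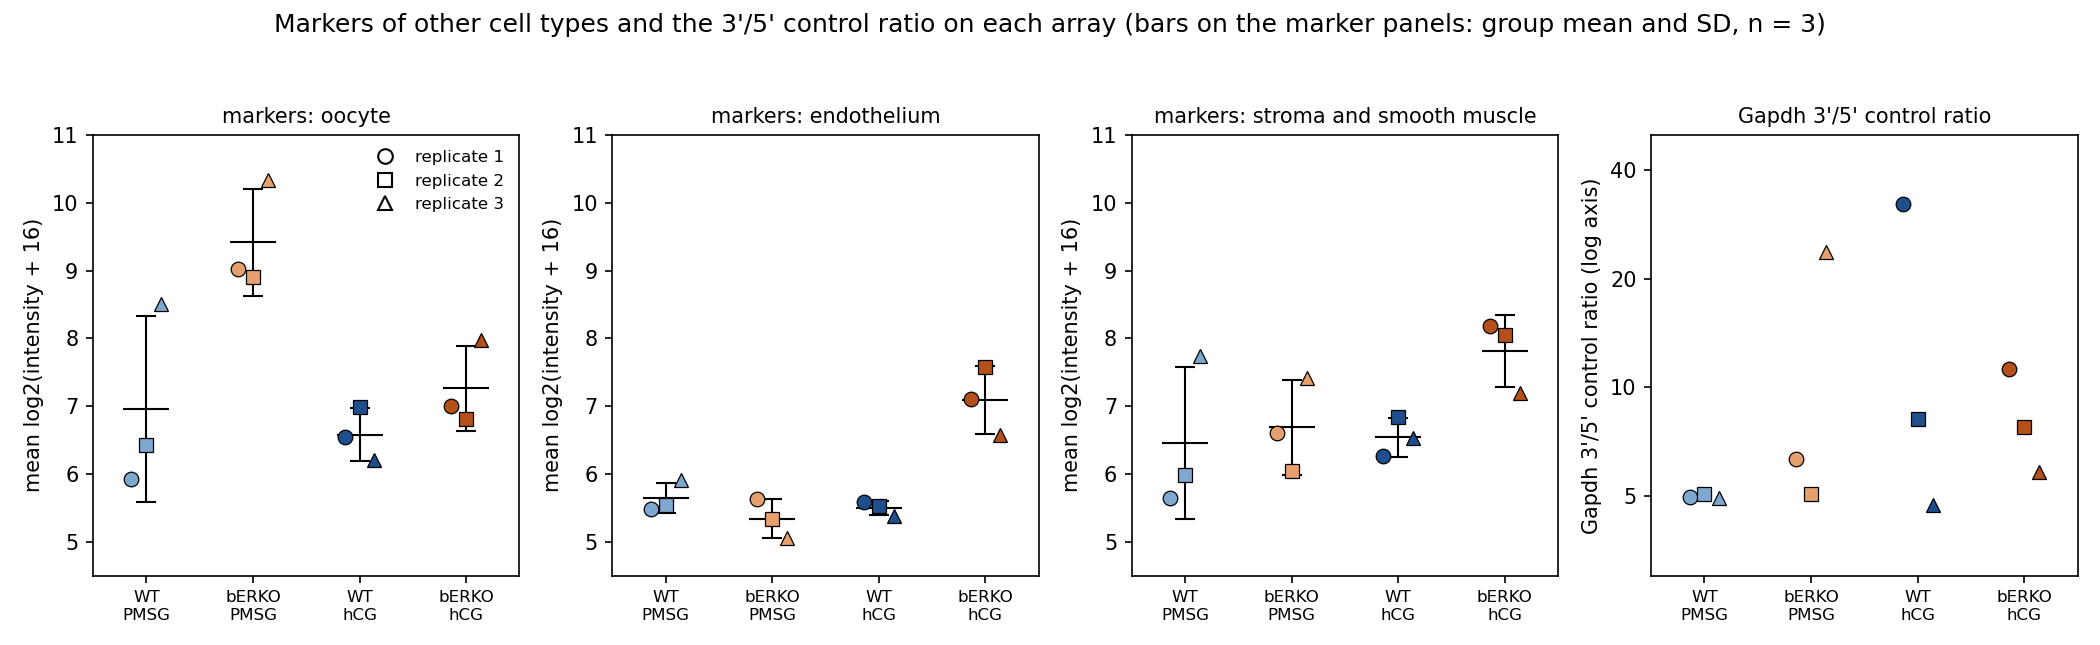
Mean log2(intensity + 16) of 3 marker lists on each array, and the Gapdh 3'/5' control ratio on a log axis, by group. Symbols mark the replicates and bars on the marker panels show the group mean and SD of 3 arrays. Oocyte markers stood at 9.02, 8.90 and 10.33 on the bERKO PMSG arrays, and endothelial markers at 7.11, 7.58 and 6.58 on the bERKO hCG arrays against 5.58, 5.52 and 5.39 on the WT hCG arrays.

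After hCG, limma called 282 genes higher and 280 lower in bERKO (562 of 18193), and for all 562 the groups did not overlap. Over all genes 24.5% did not, where chance gives 10%, and 3183 genes had an unadjusted p under 0.05. The share called higher, 50.2%, was 39.1% with values as deposited (221 higher, 344 lower) and 66.5% with each array centred on its median (356 higher, 179 lower). The count fell to 141 without WT hCG replicate 1, 307 without WT hCG replicate 2, and 143, 172 and 255 without bERKO hCG replicate 1, 2 or 3. Of the 46 named genes with a call, 16 kept it without WT hCG replicate 1, 30 and 36 without WT hCG replicate 2 and 3, and 17, 18 and 27 without bERKO hCG replicate 1, 2 and 3, all with their direction. The calls of the 10 lists held when any 1 array was left out.

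Averaged over both treatments, 7 genes were higher and 19 lower in bERKO (26 in limma, with 2311 at an unadjusted p under 0.05). Inhbb (-1.52, SE 0.20), Foxo1 (-1.31, SE 0.21), Id3 (-1.65, SE 0.20) and Akr1c14 (-1.03, SE 0.16) were lower, and Mpzl2 (3.51, SE 0.37) was higher. After PMSG, Foxo1 had means of 14.40 in WT and 14.42 in bERKO, and Mpzl2 of 5.11 and 5.09, so for these 2 genes the average carried a difference seen after hCG. Foxo1, Inhbb and Mpzl2 also passed the interaction. These genes were chosen after their values were seen. Of the calls, 26.9% were higher, against 16.7% with values as deposited (3 higher, 15 lower) and 45.5% with each array centred on its median (10 higher, 12 lower). Without 1 of the WT PMSG arrays the count was 3, 3 and 53 (replicates 1 to 3), without 1 of the bERKO PMSG arrays 0, 9 and 4, without WT hCG replicate 1 or 3 it was 10 and 50, and without 1 of the bERKO hCG arrays 2, 1 and 17. Without both arrays that stood apart it was 0.

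The third comparison addressed the response of WT granulosa cells to hCG. Ovulatory genes rose by several log2 units: the EGF-like ligand Ereg by 6.78 (SE 0.99, adjusted p = 0.00952), Ptgs2 by 6.75 (SE 1.07, adjusted p = 0.0125), the estrogen sulfotransferase Sult1e1 by 6.50 (SE 1.49, adjusted p = 0.048) and Star, which moves cholesterol into mitochondria, by 4.03 (SE 0.84, adjusted p = 0.0345). On WT hCG replicate 1 these genes measured 8.35, 8.18, 5.97 and 10.50, against 13.16, 12.23, 12.84 and 14.33 on replicate 2. Pgr had a change of 4.03 (SE 1.60) that did not pass (adjusted p = 0.222), with replicate 1 at 5.21, and was at 6.70 without that array and at 2.62 without replicate 3. The other largest rises were Peg10 (4.38, SE 0.62), Zfp365 (4.28, SE 0.84), the decay factor Smg5 (4.14, SE 0.32, adjusted p = 0.00045) and Rnd3 (4.00, SE 0.71). The largest falls were the matrix protein Comp (-4.80, SE 0.96), Igk (-4.07), Mboat1 (-3.97, SE 0.87), Tmprss13 (-3.66, SE 0.62), Astn1 (-3.62, SE 0.82), Insyn2b (-3.52, SE 0.52), Cadm3 (-3.46, SE 0.47) and Particl (-3.28, SE 0.66). Some genes had probe sets of the same sign but unlike size: Smg5 ran from 0.47 to 4.14, Mboat1 from -3.97 to -0.58 and Particl from -3.28 to -0.10.

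Immediate early genes rose as a group in WT: 2 of 19 over all genes and 9 adjusted over the list alone (mean 1.45, camera adjusted p = 1.83e-09; adjusted p = 0.128 with an estimated correlation), with Nr4a1 up by 3.01 (SE 0.59) and Egr1 by 2.70 (SE 0.58). Of 17 cumulus expansion genes and EGF-like ligands, 2 rose over all genes, Ptgs2 and Ereg, and 7 rose and 1 fell adjusted over the list alone (mean 1.74, camera adjusted p = 0.00245; adjusted p = 0.323 with an estimated correlation). Ptx3 (4.61, adjusted p = 0.0622), Tnfaip6 (4.45), Btc (4.24), Has2 (2.95) and Hbegf (-2.79) did not pass over all genes. Of these, Tnfaip6 and Btc were outside the rule for named genes and chosen after their values were seen. Ovulatory transcription factors rose as a group (mean 0.61, camera adjusted p = 0.0184; adjusted p = 0.229 with an estimated correlation), with 1 of 20 over all genes, Cebpb (1.36, SE 0.28), and 5 up and 1 down adjusted over the list alone. Klf4 (2.27), Runx1 (2.76) and Klf9 (1.30) did not pass over all genes. The list mean was 0.95 without WT hCG replicate 1. That list call was lost without WT PMSG replicate 1 (adjusted p = 0.0758) or WT hCG replicate 3 (0.205). Genes of cAMP signalling rose as a group (33 genes, mean 0.49, camera adjusted p = 0.00127; adjusted p = 0.11 with an estimated correlation), with 2 up over all genes and 3 adjusted over the list alone, the phosphodiesterases Pde4d (2.52, SE 0.47) and Pde10a (2.74, SE 0.52) among them. Heat shock genes rose as a group (15 genes, mean 0.51, camera adjusted p = 0.00513; adjusted p = 0.128 with an estimated correlation), with Hsp90aa1 (1.93, SE 0.26) and Hsph1 (1.30, SE 0.30) up over all genes, and 5 up and 1 down adjusted over the list alone. Probe sets disagreed in sign for Cebpb, Pde4d, Pde10a, Hsp90aa1 and Igk.

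Proliferation and sterol genes fell in WT. Of 30 proliferation genes, 8 fell over all genes and 9 adjusted over the list alone (mean -0.71, camera adjusted p = 7.92e-07; adjusted p = 0.128 with an estimated correlation), such as the mitotic genes Bub1 (-1.72, SE 0.25), Ccnb2 (-1.71, SE 0.28), Bub1b (-2.09, SE 0.39) and Cdk1 (-1.33, SE 0.27). Of 16 cholesterol genes, 3 fell over all genes, Fdps (-2.34, SE 0.46), Insig1 (-1.55, SE 0.29) and Stard4 (-1.43, SE 0.28), and 5 adjusted over the list alone (mean -0.77, camera adjusted p = 0.00147; adjusted p = 0.348 with an estimated correlation). Steroidogenesis had no call and moved both ways, with Star and Sult1e1 up and Akr1c18 (-2.65, SE 0.49) and Hsd11b2 (-2.06, SE 0.32) down. Its mean was 0.24 and its median -0.49, and the mean ran from 0.05 to 0.58 with 1 array left out, the highest without WT hCG replicate 1. Single members of other lists without a call passed: Adamts9 (1.73, SE 0.37), Kitl (1.38, SE 0.31), Id2 (2.19, SE 0.31) and Egln3 (3.61, SE 0.40) rose. Marker lists had no call in WT. Esr2 (-0.57), Esr1 (-0.90), Fshr (0.04) and Cyp17a1 (0.62) did not pass. Esr2 was at -0.18 without WT PMSG replicate 1, and Cyp17a1 at 0.23 and 1.06 without WT PMSG replicate 2 or 3. The sign of the Fshr value turned without WT PMSG replicate 2 (-0.05), WT hCG replicate 1 (-0.33) or WT hCG replicate 3 (-0.01), and with values as deposited (-0.02) or arrays centred on their median (-0.27).

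In WT, limma called 133 genes up and 245 down after hCG (378 of 18193), all 378 without overlap between the groups. Over all genes 24.0% did not overlap, where chance gives 10%. The share called up was 35.2%, against 43.3% with values as deposited (101 up, 132 down) and 18.1% with each array centred on its median (72 up, 325 down). The count was 62, 75 and 67 without WT PMSG replicate 1, 2 or 3, 49 without WT hCG replicate 2, 225 without WT hCG replicate 3, 580 without bERKO PMSG replicate 3, and 231 and 199 without bERKO hCG replicate 1 or 2. Without both arrays that stood apart it was 835. Of the 36 named genes with a call, 9, 10 and 11 kept it without 1 of the WT PMSG arrays and 31, 12 and 22 without WT hCG replicate 1, 2 and 3.

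The fourth comparison addressed the response of bERKO granulosa cells to hCG. The rises included the genes that rose in WT: Sult1e1 by 10.02 (SE 1.49, adjusted p = 0.00111), Ptgs2 by 9.40 (SE 1.07, adjusted p = 0.00032), Ereg by 9.33 (SE 0.99, adjusted p = 0.000239) and Star by 6.51 (SE 0.84, adjusted p = 0.000547). Pgr rose by 8.50 (SE 1.60, adjusted p = 0.00398), Ptx3, a cumulus matrix protein, by 8.35 (SE 1.13, adjusted p = 0.000706), neurotensin (Nts) by 9.09 (SE 1.53), Sfrp4 by 8.64 (SE 1.23) and the synaptic fusion protein Snap25 by 8.10 (SE 1.37). The 2 probe sets of Ptx3 ran from 0.71 to 8.35. The largest falls were Tex14 (-5.52, SE 0.56), Kctd14 (-4.84, SE 0.58), Zg16 (-4.81, SE 0.62), Tmprss13 (-4.69, SE 0.62), Lrrc10b (-4.57, SE 0.34), Insyn2b (-4.52, SE 0.52), Fbxw22 (-4.50, SE 1.12) and the ganglioside synthase St8sia1 (-4.42, SE 0.46). Fbxw22 measured 5.15, 4.55 and 8.22 in WT PMSG and 9.50, 8.97 and 11.17 in bERKO PMSG. Like the oocyte markers, it was higher in bERKO and highest on replicate 3 of both groups. Whether it came from captured oocyte RNA was not tested. The 3 probe sets of St8sia1 ran from -4.42 to -0.80. Esr1 fell by 3.45 (SE 0.32, adjusted p = 0.000155) and Fshr by 1.84 (SE 0.50, adjusted p = 0.025), whereas Esr2 (0.02) and Cyp17a1 (-0.12) did not pass. The sign of the Esr2 value turned without bERKO PMSG replicate 1 (-0.05), bERKO PMSG replicate 3 (-0.08) or bERKO hCG replicate 3 (-0.08), and its highest value was 0.18. The sign of the Cyp17a1 value turned without bERKO PMSG replicate 1 (0.13), bERKO PMSG replicate 2 (0.09) or bERKO hCG replicate 1 (0.24), and with values as deposited (0.09), and its lowest value was -0.58.

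Signalling and matrix genes rose in bERKO. Of 19 immediate early genes, 11 rose over all genes and 15 adjusted over the list alone (mean 2.74, camera adjusted p = 7.87e-12; adjusted p = 0.128 with an estimated correlation), such as Nr4a3 (4.35, SE 0.48), Nr4a1 (3.97, SE 0.59), Jun (3.13, SE 0.37) and Ier3 (4.58, SE 0.66). Of 17 cumulus expansion genes and EGF-like ligands, 10 rose over all genes, and 10 rose and 1 fell adjusted over the list alone (mean 3.34, camera adjusted p = 4.42e-06; adjusted p = 0.128 with an estimated correlation). Beside Ptgs2, Ereg and Ptx3 they included Epgn (6.71, SE 0.97), and, of other members, Has2 (4.99, SE 0.75), Tnfaip6 (7.10, SE 1.44) and Vcan (2.26). Those other members were outside the rule for this contrast and chosen after their values were seen. Of 20 ovulatory transcription factors, 11 rose and 2 fell over all genes, and 12 rose and 2 fell adjusted over the list alone (mean 1.62, camera adjusted p = 1.15e-05; adjusted p = 0.128 with an estimated correlation), with Klf4 (4.19, SE 0.57), Runx1 (4.26, SE 0.71), Fosl1 (3.70, SE 0.55) and Cited2 (1.91, SE 0.35) among the rises. Of 16 proteases and inhibitors, 7 rose and 1 fell over all genes and adjusted over the list alone (mean 1.27, camera adjusted p = 0.000217; adjusted p = 0.128 with an estimated correlation), with Adamts4 (5.21, SE 0.74), Plau (2.92, SE 0.35), Adamts9 (2.42, SE 0.37) and Timp1 (3.93, SE 0.72) among the rises. Of 33 cAMP genes, 7 rose and 4 fell, over all genes and adjusted over the list alone (mean 0.72, camera adjusted p = 0.00659; adjusted p = 0.128 with an estimated correlation), Adcyap1 (7.23, SE 1.08), Pde4b (4.01, SE 0.38), Pde10a (4.03, SE 0.52) and Pde4d (3.47, SE 0.47) among the rises.

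Steroidogenesis rose as a group in bERKO, with 6 of 13 up and 3 down over all genes and adjusted over the list alone (mean 1.79, camera adjusted p = 0.0244; adjusted p = 0.244 with an estimated correlation). Star, Sult1e1 and Fdx1, the electron donor of mitochondrial steroid enzymes (1.90, SE 0.28), rose and Akr1c14 fell (-1.92, SE 0.22). The list call was lost without bERKO PMSG replicate 3 (adjusted p = 0.0782). Cholesterol genes rose as a group, with 5 of 16 up and 1 down over all genes and 7 up and 2 down adjusted over the list alone (mean 0.86, camera adjusted p = 0.00173; adjusted p = 0.348 with an estimated correlation), Dhcr7 (2.46, SE 0.30), Cyp51 (2.13, SE 0.34) and Sc5d (3.02, SE 0.70) up and Mvk (-1.38, SE 0.35) down. Luteal markers rose as a group, 5 of 8 over all genes and adjusted over the list alone (mean 2.63, camera adjusted p = 0.000282; adjusted p = 0.128 with an estimated correlation), including Ptgfr (6.19, SE 0.79), Sfrp4, Cdkn1a (1.64, SE 0.26) and Parm1 (2.34, SE 0.65). Wnt and TGF-beta genes rose on balance, with 7 of 25 up and 4 down over all genes and 9 up and 4 down adjusted over the list alone (mean 0.87, camera adjusted p = 0.0123; adjusted p = 0.128 with an estimated correlation). Id2 (3.54, SE 0.31) and Sfrp4 rose, and Bmpr1b (-2.30, SE 0.32) and Tgfbr3 (-1.62, SE 0.28) fell. Heat shock genes rose as a group, 4 of 15 over all genes and adjusted over the list alone (mean 0.50, camera adjusted p = 0.029; adjusted p = 0.185 with an estimated correlation): Hsp90aa1 (2.0), Dnaja1 (1.13), Hsph1 (1.40) and Gadd45a (3.27, and 2.10 without bERKO PMSG replicate 3).

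Proliferation genes fell in bERKO: 1 of 30 rose and 11 fell over all genes, and 1 rose and 17 fell adjusted over the list alone (mean -0.80, camera adjusted p = 0.000744; adjusted p = 0.215 with an estimated correlation), as in Ccnb2 (-2.0, SE 0.28), Mcm6 (-1.66, SE 0.26), Bub1b (-1.87, SE 0.39) and Mcm7 (-1.27, SE 0.28). The preovulatory list had no call (mean -0.44, camera adjusted p = 0.209), with 2 of 22 up and 8 down over all genes. Foxo1 (-2.96, SE 0.29) and Inhbb (-2.74, SE 0.28) fell and Pappa (4.76, SE 0.67) rose. In hypoxia and glycolysis, also without a call, 7 rose and 5 fell over all genes, with Egln3 (6.30, SE 0.40) and Ndrg1 (2.44) up and Pdk1 (-3.72, SE 0.58) down. In the nuclear receptor list, without a call, 2 rose and 2 fell, with the glucocorticoid receptor Nr3c1 at 1.86. Probe sets disagreed in sign for Mcm6, Pde4b, Pde4d, Nr3c1, Ndrg1, Hsp90aa1, Dnaja1 and the collagen Col1a2.

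Markers of other cell types moved with the hCG response in bERKO. Endothelial markers rose, 5 of 12 over all genes and 7 adjusted over the list alone (mean 1.75, camera adjusted p = 3.37e-06; adjusted p = 0.119 with an estimated correlation): Emcn by 3.63 (SE 0.35), Kdr by 3.37 (SE 0.59), Flt1 by 2.10 (SE 0.36) and Pecam1 by 2.17 (SE 0.49). Stromal markers rose as a group, with 2 of 15 over all genes, Col1a2 (3.91, SE 0.88) and Pdgfrb (2.62, SE 0.81), and 1 adjusted over the list alone (mean 1.13, camera adjusted p = 0.017; adjusted p = 0.525 with an estimated correlation). Col3a1 (3.35) and Dcn (2.11) did not pass, and the list call was lost without bERKO PMSG replicate 2 (adjusted p = 0.118). Oocyte markers fell, 7 of 13 over all genes and 10 adjusted over the list alone (mean -2.16, camera adjusted p = 0.0014; adjusted p = 0.42 with an estimated correlation), with Nlrp14 at -2.98, Zar1 at -2.71, Nlrp5 at -2.59 and Ooep at -2.40. Of the theca list, without a call, Hhip (3.64, SE 0.76) rose and Ptch1 (-1.52) and Aldh1a1 (-1.55) fell, and of the leukocyte list, also without one, Cd52 (1.84) and Lyz2 (2.06) rose. Erythrocyte and surface epithelium lists had no call and 0 members passing (camera adjusted p = 0.21 and 0.885).

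In bERKO, limma called 1283 genes up and 2164 down after hCG (3447 of 18193). The groups did not overlap for 3409 of them, and over all genes for 36.2%, where chance gives 10%. The share called up was 37.2%, against 43.0% with values as deposited (1439 up, 1906 down) and 24.3% with each array centred on its median (964 up, 3005 down). Of the 78 named genes with a call, at least 69 kept it without any 1 of the arrays. No left-out array changed the count by over 1.5 times.

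**Figure D3:**
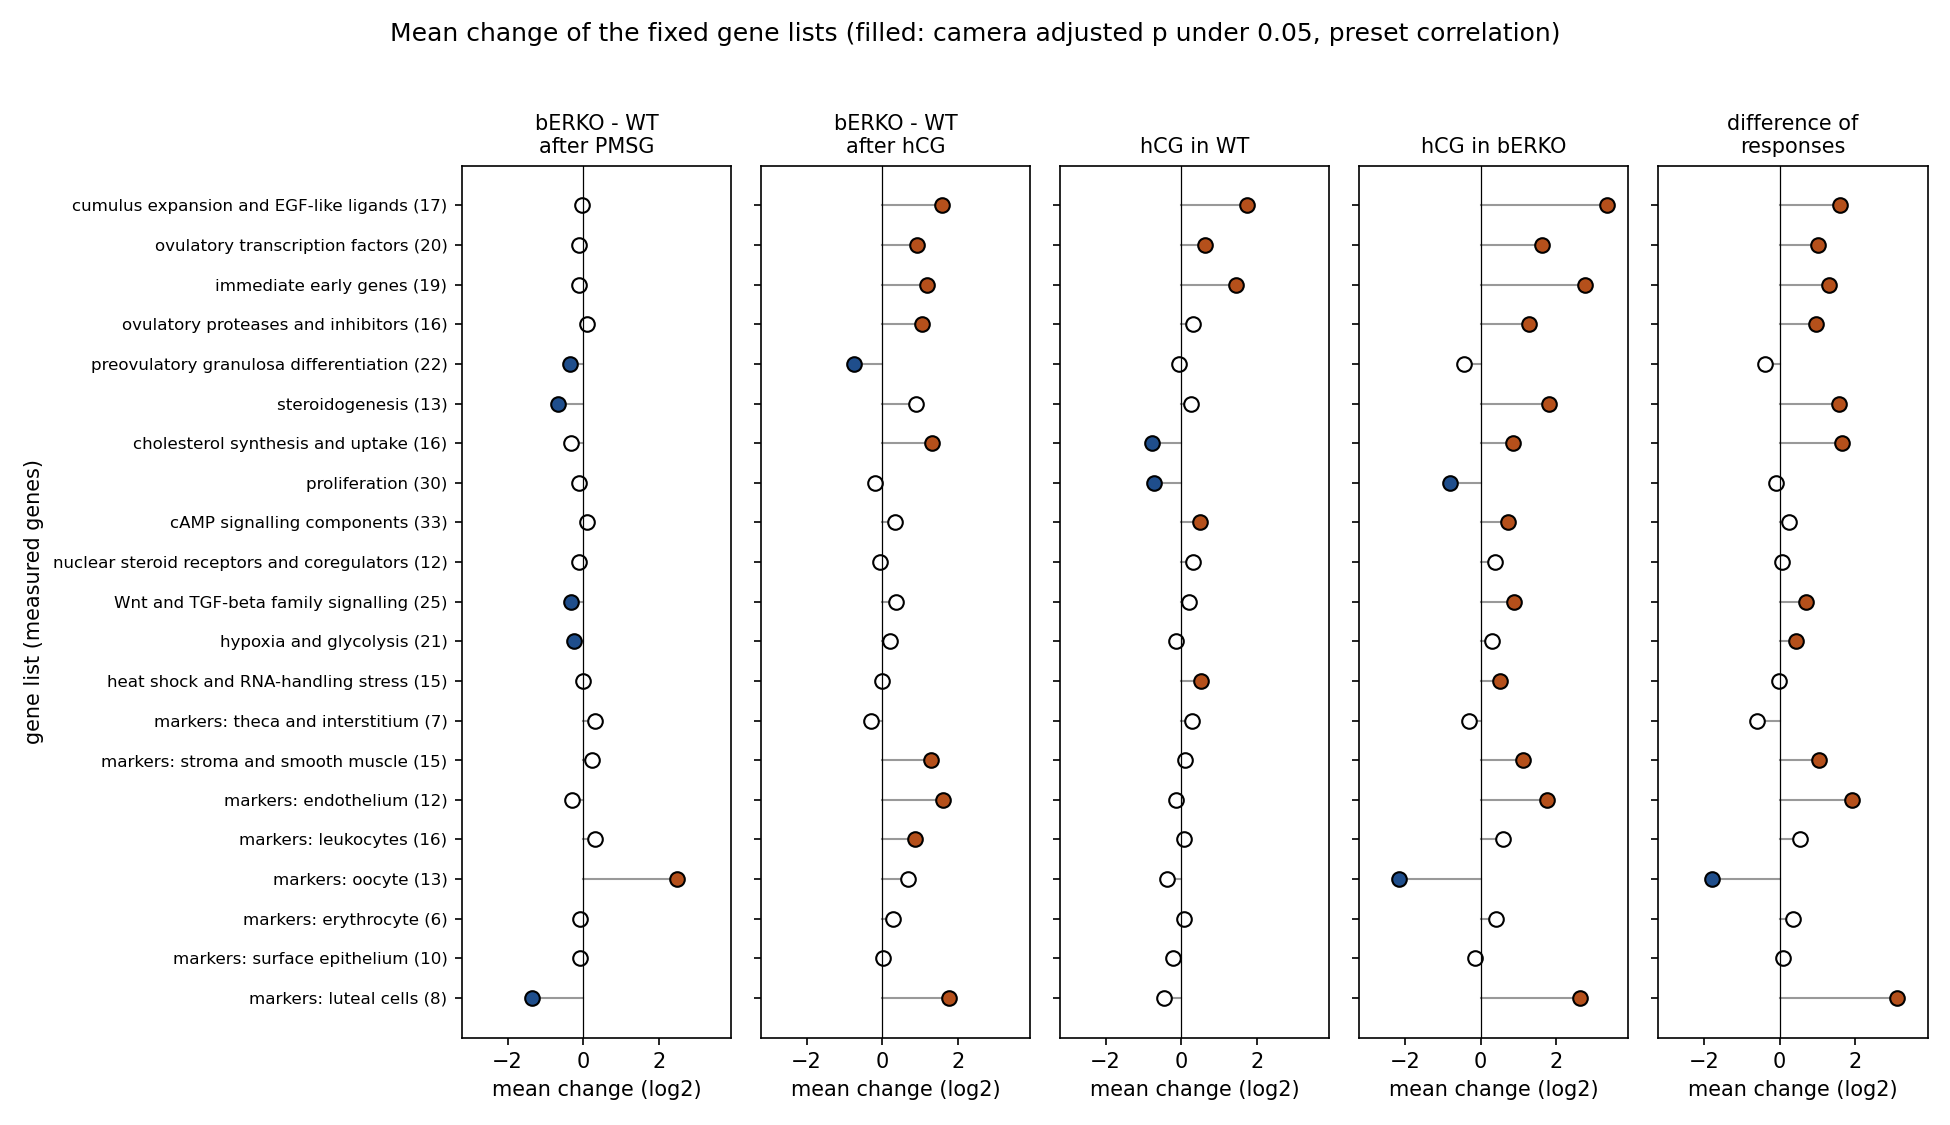
Mean log2 change of each of the 21 gene lists on the horizontal axes, 1 panel per contrast, with the number of measured genes beside each list. Filled points passed camera with a preset correlation. Cumulus expansion genes and EGF-like ligands had means of 1.74 in WT and 3.34 in bERKO, and oocyte markers one of 2.46 for bERKO against WT after PMSG.

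The responses were then set against each other. Across 18193 genes, which are not independent replicates, the responses of WT and bERKO correlated at r = 0.411. Of the genes called, 245 were called in both genotypes in the same direction: 87 up, against 9.4 for independent lists, and 158 down, against 29.1. Because both tests use the same spread per gene, the overlap expected by chance can be higher than these values. The count with only the compared groups in each fit is given below. The count was 49, 59 and 52 without 1 of the WT PMSG arrays, 382, 40 and 142 without 1 of the WT hCG arrays, and 151 and 137 without bERKO hCG replicate 1 or 2. Over the 3488 genes that responded on average (1221 up, 2267 down), the mean response was 0.94 in WT and 1.73 in bERKO, a difference of 0.79 (exact permutation p = 0.005, two-sided, the smallest that 400 arrangements can give). The median over these genes of the signed difference was 0.64, and 77.8% of the genes responded more in bERKO. Without WT hCG replicate 1 the difference was 0.64 (exact permutation p = 0.005).

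The interaction tested each gene for a different response. Sfrp4 responded more in bERKO by 9.05 (SE 1.74, adjusted p = 0.0339): it had a mean of 10.87 in WT and 5.57 in bERKO after PMSG, and of 10.45 in WT and 14.21 in bERKO after hCG. It measured 6.74, 11.44 and 13.17 on the WT hCG arrays, and without replicate 1 its WT change turned from -0.42 to 1.44 and the difference was 7.20. Without WT hCG replicate 3 that WT change was -1.78. Comp, with a difference of 8.53 (SE 1.35, adjusted p = 0.0136), and Cadm3, with 7.12 (SE 0.66, adjusted p = 0.00364), fell in WT and rose in bERKO. Comp measured 5.38, 5.80 and 10.07 on the WT hCG arrays. Cadm3 lay at the floor of 4 on the bERKO PMSG arrays, so the size of its difference depends on the offset. Cemip (7.43, SE 1.46), Mpzl2 (7.06, SE 0.74), Ptgfr (7.06, SE 1.12), Lipg (6.60, SE 1.28) and the synaptic adhesion protein Lrrtm3 (6.35, SE 0.78) followed. The 3 probe sets of Cemip ran from 0.54 to 7.43. Cemip and Lipg had the array pattern shared with the stromal markers that is described above. Sfrp4 and Ptgfr had that order of arrays too, unlike Comp, Cadm3, Mpzl2 and Lrrtm3. The most negative differences were those of Limch1 (-5.63, SE 0.89), Kazald1 (-4.93, SE 0.79), Tex14 (-4.92, SE 0.79), Cldn11 (-4.77, SE 0.99), the phospholipase Pla2g1b (-4.69, SE 1.01), the collagen Col11a1 (-4.67, SE 0.78), Cnnm1 (-4.63, SE 0.84) and the ankyrin Ank3 (-4.55, SE 0.72). Esr1 responded more negatively in bERKO, by -2.55 (SE 0.45, adjusted p = 0.0236). For Ptgs2 (2.65, adjusted p = 0.441), Pgr (4.47, adjusted p = 0.381), Fshr (-1.88, adjusted p = 0.235), Esr2 (0.58) and Cyp17a1 (-0.74) the responses were not shown to differ. Without WT hCG replicate 1 the difference was 1.06 for Ptgs2 and 1.79 for Pgr. For Esr2 it was 0.19 without WT PMSG replicate 1, and for Cyp17a1 it ran from -1.20 to -0.35 with 1 array left out.

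Steroid and sterol genes responded more positively in bERKO as groups. Steroidogenesis had a mean difference of 1.55 with 2 of 13 over all genes, and 5 more positive and 1 more negative adjusted over the list alone (camera adjusted p = 0.00196; adjusted p = 0.128 with an estimated correlation): Hsd17b7 (3.86, SE 0.59) and Akr1c18 (3.17, SE 0.69) passed, and Cyp11a1 (6.60, adjusted p = 0.0526) did not. Cholesterol genes had a mean difference of 1.63 with 2 of 16 over all genes, Insig1 (1.99, SE 0.41) and Idi1 (2.30, SE 0.48), and 13 more positive and 1 more negative adjusted over the list alone (camera adjusted p = 9.49e-09; adjusted p = 0.128 with an estimated correlation). Fdps (2.88) and Dhcr7 (1.84) did not pass over all genes. Luteal markers had a mean difference of 3.10 with 3 of 8 over all genes and 5 adjusted over the list alone (camera adjusted p = 6.62e-06; adjusted p = 0.128 with an estimated correlation).

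Ovulatory lists responded more positively in bERKO as groups, with few single genes past the threshold. Cumulus genes and EGF-like ligands had a mean difference of 1.60 (camera adjusted p = 0.0003; adjusted p = 0.215 with an estimated correlation) and 0 members passing by either count, where limma's interaction had 2783 genes at an unadjusted p under 0.05. Without WT hCG replicate 1, the array that stood apart, that mean was 0.89. Il6 was at 1.60. Ovulatory transcription factors had 1.01 (camera adjusted p = 0.00171; adjusted p = 0.128 with an estimated correlation), 0 over all genes and 5 adjusted over the list alone, with Bcl6 at 1.83 and Fosl1 at 2.72, and a mean of 0.68 without WT hCG replicate 1. Immediate early genes had 1.29 (camera adjusted p = 0.0003; adjusted p = 0.348 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone, with Jun at 2.08 and Dusp1 at 4.54. Proteases had 0.96 (camera adjusted p = 0.0036; adjusted p = 0.215 with an estimated correlation), with Adamts4 passing (5.18, SE 1.04) and 3 adjusted over the list alone. Wnt and TGF-beta genes had 0.69 (camera adjusted p = 0.0457; adjusted p = 0.135 with an estimated correlation), with Sfrp4 over all genes and 5 more positive and 1 more negative adjusted over the list alone. Hypoxia and glycolysis had 0.44 (camera adjusted p = 0.0118; adjusted p = 0.418 with an estimated correlation), with Egln3 (2.68, SE 0.57) and Ndrg1 (2.73, SE 0.56) over all genes and adjusted over the list alone, and a mean of 0.28 without bERKO PMSG replicate 3. In lists without a call, Foxo1 (-2.66, SE 0.41) and Inhbb (-2.44, SE 0.40) responded more negatively and Pde4b (2.77, SE 0.54) more positively, though the probe sets of Pde4b ran from -0.41 to 3.16.

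Marker lists differed too. Endothelial markers responded more positively in bERKO, by a mean of 1.90 (camera adjusted p = 4.35e-07; adjusted p = 0.11 with an estimated correlation), with Emcn (3.70, SE 0.50) and Cdh5 (4.03, SE 0.70) over all genes and 5 of 12 adjusted over the list alone. Stromal markers had 1.04 (camera adjusted p = 0.0423; adjusted p = 0.569 with an estimated correlation; mean 0.40 without WT PMSG replicate 3) and oocyte markers -1.78 (camera adjusted p = 0.00204; adjusted p = 0.435 with an estimated correlation), with 0 members passing by either count. Theca markers had no call, at -0.58. Proliferation and heat shock lists had no call either.

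Limma called 239 genes with a different response, 123 more positive and 116 more negative in bERKO. The count was 108, 133 and 90 without 1 of the WT PMSG arrays, 118 and 141 without bERKO PMSG replicate 1 or 3, 115, 125 and 408 without 1 of the WT hCG arrays, and 89 and 81 without bERKO hCG replicate 1 or 2. Without both arrays that stood apart it was 120, of which 88 were among the 239. Of the 29 named genes with a call, between 12 (without bERKO hCG replicate 2) and 27 (without WT hCG replicate 3) kept it. The Wnt and TGF-beta list lost its call without WT PMSG replicate 2 or 3 (adjusted p = 0.0536 and 0.104), bERKO PMSG replicate 1, 2 or 3 (0.0535, 0.0836 and 0.0517), WT hCG replicate 2 (0.0625) or bERKO hCG replicate 2 (0.069). The stromal list lost it without WT PMSG replicate 3 (0.393), bERKO PMSG replicate 1 or 2 (0.0803 and 0.246), WT hCG replicate 1 or 3 (0.135 and 0.0543) or bERKO hCG replicate 1 or 2 (0.0976 and 0.0695), and hypoxia and glycolysis without bERKO PMSG replicate 3 (0.0927).

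**Figure D4:**
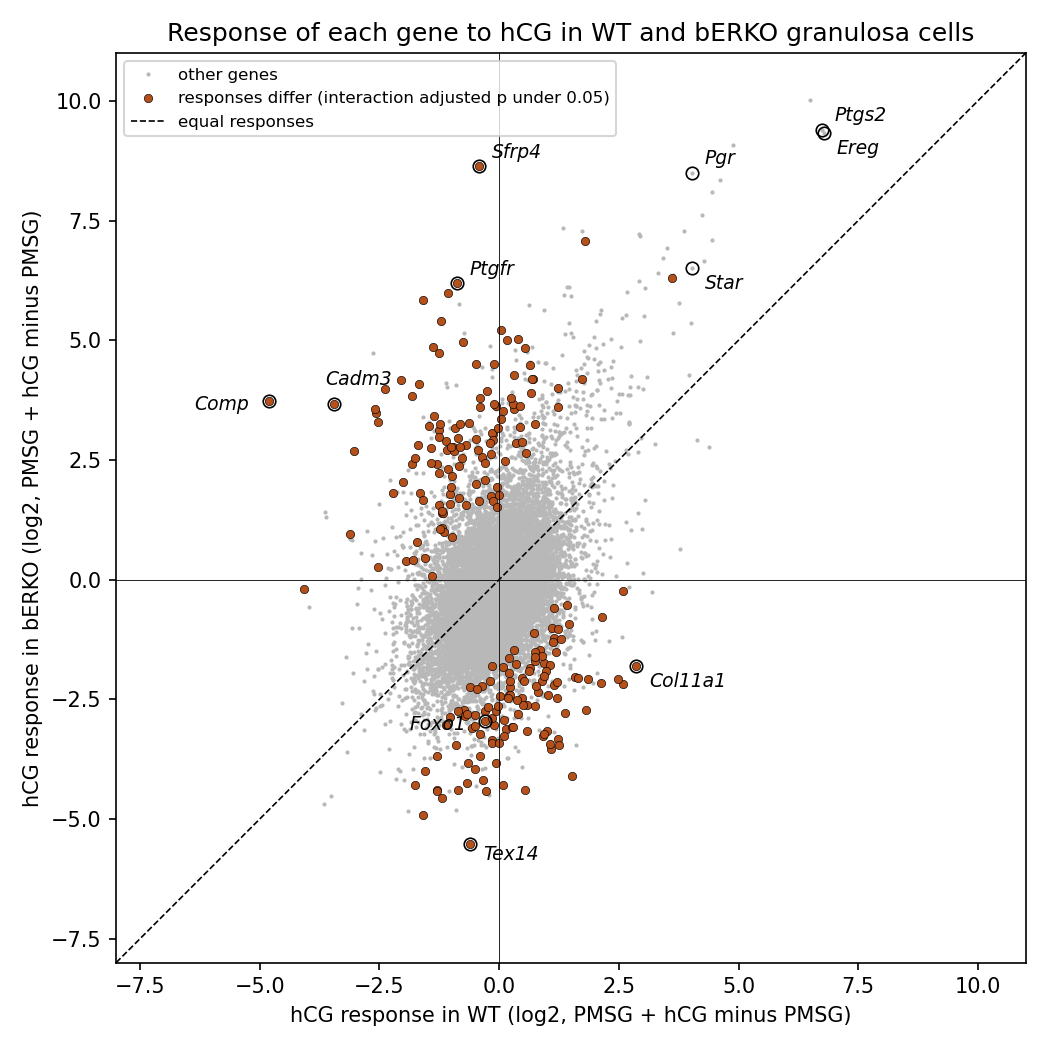
Change of each gene from PMSG to hCG (log2) in WT on the horizontal axis and in bERKO on the vertical axis. Large points are the 239 genes whose response differed in limma, circles mark named genes, and the dashed line marks equal responses. Ptgs2 (6.75 in WT, 9.40 in bERKO) and Ereg (6.78 and 9.33) rose in both genotypes, while Comp (-4.80 and 3.73) and Cadm3 (-3.46 and 3.66) moved in opposite directions.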

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

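The tests of a wrong label, of a swap, of replicate 1 alone, of other cell types and of both oocyte explanations were chosen only after the results were seen; those of degraded RNA, of the scaling and of other splits were not.

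The hCG response differed between genotypes for 239 genes by the interaction test, and its mean size differed by 0.79 log2 units. Of 100 splits of the genotypes within each treatment, 1, the real one, gave that many genes, and the highest other gave 48. These splits test for any genotype difference in either treatment, not for the interaction alone. Mixing the genotypes also adds real differences to the spread, which lowers the other counts, so the splits do not by themselves exclude chance. The named genes singled out by this test had differences of 9.05 (Sfrp4), 8.53 (Comp), 7.43 (Cemip), 7.12 (Cadm3), 7.06 (Mpzl2), 7.06 (Ptgfr), 6.60 (Lipg) and 6.35 (Lrrtm3). On the negative side they had -5.63 (Limch1), -4.93 (Kazald1), -4.92 (Tex14), -4.77 (Cldn11), -4.69 (Pla2g1b), -4.67 (Col11a1), -4.63 (Cnnm1) and -4.55 (Ank3). Gene lists singled out by camera had mean differences of 1.60 (cumulus expansion and EGF-like ligands), 1.01 (ovulatory transcription factors), 1.29 (immediate early genes), 0.96 (ovulatory proteases), 1.55 (steroidogenesis), 1.63 (cholesterol), 0.69 (Wnt and TGF-beta), 0.44 (hypoxia and glycolysis), 1.04 (stroma, 0.40 without WT PMSG replicate 3), 1.90 (endothelium), -1.78 (oocyte) and 3.10 (luteal). None of these list calls held with an estimated correlation. By exact permutation of genotype within treatment, adjusted over the 21 lists, steroidogenesis, Wnt and TGF-beta and luteal lists differed (p = 0.005 each, the smallest possible, adjusted p = 0.035). The other 9 did not pass, with adjusted p from 0.0788 (endothelium) to 0.406 (stroma). Part of each difference that passed was a lower level in bERKO after PMSG. For steroidogenesis, Wnt and TGF-beta and luteal lists, bERKO minus WT was -0.67, -0.33 and -1.35 after PMSG and 0.88, 0.355 and 1.75 after hCG. bERKO PMSG replicate 3 was the lowest PMSG array for steroidogenesis (9.68) and luteal markers (7.64), but not for the Wnt and TGF-beta list. The means of the lists that differed were highest within WT PMSG and lowest within bERKO hCG on replicate 3, as were the stromal markers. For luteal markers they were 9.25, 9.01 and 9.73 in WT PMSG and 10.78, 10.81 and 10.25 in bERKO hCG. The lists that differed share genes and are not separate results. Sfrp4 (9.05) is in the Wnt and TGF-beta list and in the luteal list, and Akr1c18 is in the steroidogenesis and luteal lists.

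The larger response in bERKO could come from WT hCG replicate 1 alone, from other cell types on the bERKO hCG arrays, or from the scaling. Without that array the difference in size was 0.64 (exact permutation p = 0.005, the smallest that 200 arrangements can give), and with the other scalings it was at least 0.80 (p = 0.005), which argues against that array or the scaling as the whole cause. Other cell types stay open: endothelial markers rose on those arrays, though their response was not shown to differ by this test (adjusted p = 0.0788). The cumulus list was tested on the assumption that such cells would not raise it. That was not checked for its members, so the list cannot decide the question. Its response was larger in bERKO by 1.60 and, without WT hCG replicate 1, by 0.89, neither passing after adjustment (exact permutation adjusted p = 0.105 each). A stronger or earlier response of cells without estrogen receptor beta remains a hypothesis, and with 1 time point these cannot be separated here. An exchange of the genotype labels between the hCG groups would turn the interaction into the average genotype difference. That split called 239 genes for the average, against 26 with the labels as given. These counts cannot tell an exchange from a different response. After hCG, Esr2 measured 8.68, 9.52 and 8.78 in WT and 8.34, 8.13 and 8.53 in bERKO. That order goes with the labels, but Esr2 did not pass, so the labels of those arrays were checked only in part.

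WT hCG replicate 1 stood apart from the other arrays of its group. Over 1009 genes rising in bERKO its mean lay only 0.3 SDs of the WT PMSG arrays above their mean, but its changes followed those of the other WT hCG arrays (correlation 0.29, against -0.03 to 0.02 for WT PMSG arrays in its place), and over 1591 falling genes its mean moved by 5.0 SDs, which argues against a wrong label on cells that saw no hCG. A swap with a WT PMSG array is argued against, since the lowest of the other WT hCG arrays lay 13.8 SDs above the highest WT PMSG array. Degraded RNA or poor amplification stays open: its Gapdh 3'/5' ratio of 32.16 was the highest of the 12 arrays, and the correlation of its deviations with those of bERKO PMSG replicate 3, 0.032 across genes, tested only a signature shared with that array. That bound was too narrow, because the arrays differ in kind: bERKO PMSG replicate 3 had an Actb ratio of 1.61 and a median signal of 49.1, against 1.02 and 85.2 here. A late or weak hCG response of the animals behind this array may also account for it and was not tested.

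Oocyte markers were higher in bERKO after PMSG by a mean of 2.46. Oocyte RNA captured with the granulosa cells is a candidate explanation: within groups the 13 markers moved together, with a mean correlation of 0.57 between them, against at most 0.22 in random sets of 13 genes of the same levels. Genes that granulosa cells express together would do the same, so that test does not set the 2 apart. A rise with low signal quality stays open: bERKO PMSG replicate 3, with a Gapdh 3'/5' ratio of 23.74, had the highest mean of the markers (10.33). Without that array the difference was 2.01 (SE 1.02, 95% interval over arrays -1.25 to 5.26). Other arrays did not follow the ratio. WT hCG replicate 1, at 32.16, had a marker mean of 6.55, against 6.98 and 6.20 on the other WT hCG arrays. WT PMSG replicate 3, at 4.91, had a marker mean of 8.51. How many of these genes granulosa cells express themselves was not analysed here, so a higher expression in bERKO granulosa cells remains open as a hypothesis.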

How the results depend on the processing

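The values as deposited and the fit without the 2 arrays that stood apart were chosen only after the results were seen. Of 191 calls of named genes, counted once per comparison, 0 reversed under any setting; 190 were kept with array weights, 177 with median-centred arrays, 172 with values as deposited, 151 with the replicate block, 122 with log2(value + 1), 90 at 0.01, 146 without both arrays apart, and 124 to 168 without 1 array. The medians of all genes moved by -0.19 for hCG in bERKO and -0.11 for the interaction in the normalized values, by -0.11 for genotype after hCG in the values as deposited, and, with median-centred arrays, by 0.24 after PMSG, 0.14 on average, -0.22 for hCG in WT, -0.41 for hCG in bERKO and -0.20 for the interaction, so list changes are relative to the other genes. In what follows, after PMSG, after hCG and average are the genotype counts, and shared is the count called in both genotypes in the same direction. Values as deposited gave 7 after PMSG, 233 for hCG in WT, 162 shared and 3 lists after PMSG. Median-centred arrays gave 5 after PMSG. Without genes under the median level there were 5 after PMSG, 56 on average, 934 for hCG in WT, 376 for the interaction, 638 shared and r = 0.533; without genes under the lower quartile of level 4, 47 on average and 372 shared. With trend and robust, counts were 22 after PMSG, 947 after hCG, 130 on average, 822 for hCG in WT, 542 for the interaction and 538 shared. Array weights gave 1239 after hCG, 66 on average, 1598 for hCG in WT, 420 for the interaction, 924 shared and r = 0.473. With only the compared groups in the fit, there were 1, 219, 31 for hCG in WT and 14 shared. At an adjusted p under 0.01 limma gave 0 after PMSG (1733 at an unadjusted p under 0.05), 93 after hCG, 0 on average (2311), 50 for hCG in WT, 1572 for hCG in bERKO, 35 for the interaction and 32 shared, by the stricter threshold itself. The mean of probe sets gave 1 after PMSG and 7 on average, and every probe set 4 and, for hCG in bERKO, 6624, where more features were tested. With log2(value + 1), limma gave 0 after PMSG, 225 after hCG, 0 on average, 140 for hCG in WT, 95 for the interaction, 101 shared and r = 0.313; with log2(value + 64) they were 12, 882, 74, 870, 454, 586 and r = 0.477. Without both arrays apart there were 7 after PMSG, 259 after hCG, 0 on average, 835 for hCG in WT, 120 for the interaction, 605 shared and r = 0.523. Leaving out 1 array at a time gave 0 to 26 after PMSG, 141 to 684 after hCG, 0 to 53 on average, 49 to 580 for hCG in WT, 81 to 408 for the interaction, 40 to 382 shared and r from 0.290 to 0.518. With an estimated correlation 0 lists passed in each of the 5 contrasts, and with fry 3 after PMSG and 7 for the interaction. Of genes without a call, Esr2 for hCG in bERKO reversed to -0.24 (median-centred), -0.093 (weights) and -0.080 (without both arrays apart), and from -0.082 to 0.18 without 1 array. Fshr for hCG in WT reversed to -0.018 (as deposited), -0.27 (median-centred), -0.34 (weights) and -0.33 (without both), and from -0.33 to 0.46 without 1 array. Cyp17a1 for hCG in bERKO reversed to 0.094 (as deposited), and from -0.58 to 0.24 without 1 array, and after PMSG it ran from -0.033 to 0.82 without 1 array. After PMSG, Akr1c14 reversed to 0.090 (median-centred), Pgr to 0.26 (mean of probe sets), and Ptgs2 to -0.10 (weights), -0.41 (without both), and from -0.41 to 0.65 without 1 array. The cause was not tested, except as stated.

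The labels number the replicates of each group alike. The 18 same-numbered pairs of arrays had deviations correlated at -0.08 to 0.12, and 6 of 12 arrays lay closest to their own number, so the numbers do not pair the arrays. With the replicate number as a block the counts were 3 on average, 148 for hCG in WT, 129 for the interaction and 113 shared. Weak signals limit the dim genes: 18.7% to 30.0% of an array's signals lay under 16.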

Other observations

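The splits named here were planned. The sets of genes described in the next 2 paragraphs, and the array left out in them, were chosen after their values were seen.

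A small set of genes responded to hCG in opposite directions, each past the threshold in both genotypes and in the interaction. Of 8 such genes, 4 fell in WT and rose in bERKO: Comp, a cartilage matrix protein (-4.80 and 3.73), Cadm3 (-3.46 and 3.66), Lrp11, of the LDL receptor family (-3.03 and 2.69), and the G protein subunit Gnao1 (-1.17 and 1.39). The other 4 rose in WT and fell in bERKO: the fibrillar collagen Col11a1 (2.87 and -1.80), the ubiquitin ligase Hecw2 (1.66 and -2.06), Wipf3, which binds the actin regulator WASP (2.13 and -2.16), and Crispld2 (1.11 and -1.0). Standard errors ran from 0.25 for Crispld2 to 0.96 for Comp, over 3 arrays per group. Comp measured 5.38, 5.80 and 10.07 on the WT hCG arrays, so its fall in WT was far smaller on replicate 3. Cadm3 lay at the floor of 4 in bERKO after PMSG. After PMSG, Comp had means of 11.89 in WT and 6.62 in bERKO and Lrp11 of 10.52 and 6.98, but of the 8 genes 1, Cadm3, passed between the genotypes there. Genes picked for opposite responses tend to start apart. An exchange of the genotype labels between the hCG groups would give such responses too, and the gene counts cannot exclude it.

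Averaged over both treatments, further genes were lower in bERKO in limma. They included the erythroid and brain ankyrin Ank1 (-2.41, SE 0.35), the adhesion molecule Kirrel3 (-2.26, SE 0.36), the Wnt pathway protein Dixdc1 (-2.20, SE 0.36), the mitochondrial malic enzyme Me2 (-1.75, SE 0.26), the adhesion receptor Adgrg1 (-1.64, SE 0.25) and the anti-apoptotic gene Bcl2l1 (-1.61, SE 0.23). The cadherin Cdh11 (1.79, SE 0.25), Tcl1 (2.01, SE 0.33) and Fam110c (2.11, SE 0.34) were higher. Adjusted p ran from 0.0295 to 0.0437 for these 9 genes. Bcl2l1 had means of 8.81 in WT and 8.78 in bERKO after PMSG, and of 9.63 and 6.44 after hCG, so its average carried a difference seen after hCG. The means of the others lay apart in the same direction in both treatments, though not evenly. Adgrg1 had 10.75 and 10.08 after PMSG and 9.96 and 7.35 after hCG. Tcl1 was highest in bERKO after PMSG (7.98), as were the oocyte markers (9.42). Without bERKO PMSG replicate 1, 0 genes passed in limma for this average.

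For the comparisons of 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. After PMSG, 2 splits gave 2 genes or more, the real one with 2 and the highest other with 2. For bERKO against WT after hCG, 1 split, the real one, gave 562 genes and the highest other 0. For hCG in WT, 1 split, the real one, gave 378 and the highest other 0, and for hCG in bERKO, 1 split, the real one, gave 3447 and the highest other 0. For the average over both treatments, 3 of 100 splits gave 26 genes or more, the real one with 26 and others with 28 and 239. That share lies under 0.05, but the split with 28 mixed the genotypes and gave as many, so chance is not excluded for the real count. The split with 239, the highest other, exchanged the genotypes after hCG and so counted the interaction, which points to a structure of the samples larger than the average difference.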
